A study of Homo sapiens with 4 samples.

How the data were processed

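Gene expression was measured by RNA sequencing in 4 libraries of human brain: 2 of whole tissue and 2 of a matched fraction enriched for brain microvessels. Per the labels' protocols, that fraction was prepared from cerebral cortex by homogenising the tissue and centrifuging it, and total RNA was turned into cDNA with a NuGEN Ovation kit before SOLiD library preparation. The groups and the replicate numbers were taken from the sample titles.

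The authors deposited 1 table of gene-level values with a column for each library, and these were read as FPKM (reads scaled by transcript length and by library depth). Bowtie and Cufflinks are named, with the human build hg19, per the submitters' processing notes. Their versions, the gene annotation, the filters and the treatment of strand and of reads with several matches are not given in the sources used here. The unit is not written in the file header. It was taken from the named tool and from the values. Over 323 olfactory receptor genes with a locus under 1100 bp, which have a single coding exon and are silent in most tissues, each value above 0 times the locus length was a whole multiple of 1 constant per library, within 0.02 of a read, in 100% of cases. FPKM divides reads by transcript length and by library depth, so a gene that takes a large share of a library lowers every other value in it. Reads of near-identical copies (paralogs, pseudogenes, histone, tubulin and MTRNR2L genes) and of overlapping genes can be assigned to either copy, and such genes are uncertain.

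The constant gives the depth of a library if no other scaling was applied: 7.39 M reads (M for mega) for whole brain 1, 4.49 M for whole brain 2, 6.95 M for microvessel 1 and 1.98 M for microvessel 2. On a 1 kb gene, 1 read equalled 0.135, 0.223, 0.144 and 0.505 FPKM in that order, and the limit that a count of 0 allows, taken as 3 reads, was 0.406, 0.669, 0.432 and 1.52 FPKM. The olfactory receptor genes gave a background level in each library, with an exact Poisson 95% interval. These intervals and limits cover counting error only.

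The table held 23033 entries for 21670 symbols. Where a symbol had several entries (1363 were surplus), the entry of the highest mean was used, and 330 entries carried joined names of overlapping genes and were kept under the joined name. Coordinates are those of the table on hg19, counted from 1. Gene names on the lists were matched to older symbols through a RefSeq gene table, and transcript lengths came from GENCODE release 29 by symbol, both of a later build and used for no coordinates. Splicing and isoforms, which the series title names, were not analysed here. Y-linked genes, XIST and TSIX were left out of all printed values.

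Values were analysed as log2(FPKM + 0.5), for the 19420 genes with a mean of at least 0.5 FPKM over the 4 libraries. A fold change is on this scale and understates the change of low genes. The test was limma 3.58.1 (R 4.3.3; moderated test with an intensity trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05), with no further scaling. The fit without a pair term was the one fixed as the main test, and the fit with the replicate number as a block is called the paired fit. The series design calls the microvessel samples matched to the tissue samples without saying which belong together, so the pairing rests on the shared numbers. Libraries of the same number deviated from their group means together (Pearson r = 0.434 across genes). Both libraries numbered 2 also had a lower implied depth and a higher background than those numbered 1, and such shared traits can give a correlation too. It therefore cannot show that libraries of the same number came from the same tissue. For the genes named here, the paired result is given beside the unpaired one wherever it changes a call over all genes tested. Nothing states that the 2 replicates of a group came from separate donors. The p-values of single genes therefore rest on the spread between these samples, which can be technical, and on the variance of other genes. An exact permutation of 2 against 2 libraries cannot give a p below 0.333. The unpaired fit leaves 2 residual degrees of freedom per gene and the paired fit 1. Both therefore lean on variance that limma borrows from other genes, which counted as 10.3 degrees of freedom in the unpaired fit.

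Both tests were run on simulated data with the libraries' own pair differences, in which 200 of 19420 genes were changed. The changed genes had a mean of at least 2 FPKM. Each pair difference was made the same in both groups and the noise even across libraries, which favours the paired fit. In the data the deviations correlated at r = 0.434 and depth differed between libraries, so the recovered shares hold for the simulation only. The unpaired fit recovered 0% of the 2-fold, 0% of the 4-fold and 80.3% of the 16-fold changes with 0 false calls, and the paired fit recovered 16.4%, 94.0% and 100% with 8 false calls.

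Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, one way. Camera compares the members of a list with all other genes. At the preset correlation its p-value rests on the spread across genes and on that assumed value. The estimated correlation ranged from -0.066 (receptor-mediated transport) to 0.917 (oligodendrocyte precursors). It was 0.626 for endothelial, 0.448 for pericyte and smooth muscle and 0.745 for neuron markers. Adjustment was over the 25 lists with members to test. They were the ABC and SLC families by symbol, and transporter lists for efflux and uptake at the blood-brain barrier, neurons and glia. Marker lists stood for endothelium, pericytes and smooth muscle, perivascular fibroblasts, neurons, astrocytes, oligodendrocytes and their precursors, microglia, erythrocytes, leukocytes, and choroid plexus and ependyma. Further lists held genes of tight junctions, basement membrane, receptor-mediated transport, Wnt signalling, endothelial activation, the immediate early and stress response, drug metabolism and ribosomal proteins. The mitochondrially encoded genes, a further list, had 0 members under their symbols in the table. Python with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for depth, checks and figures.

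The lists, the design, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest changes in each direction among genes past the threshold with the same sign in both pairs, and the 4 ABC and 6 SLC genes of the largest change in each direction under the same condition. It also took the 5 most abundant ABC and SLC genes of the microvessel group, 23 fixed marker and transporter genes, and up to 3 further members of each list with the smallest p. Places left open because too few genes passed were filled with the largest changes of the same sign in both pairs. Genes named outside this rule were chosen after their values were seen, and they are CD34, PODXL, STMN2, RGS5, FLT1, TBX18, EBF1, MECOM, ADAMTS1, PVALB, TAC3, IL6, HSPH1, EGR1, DNAJB1, FOSB, EGR2, ABCA8, MTRNR2L1, SLC25A4 and SLCO1C1.

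The alternatives fixed beforehand were the paired fit, pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 2 FPKM, quantile normalisation, equal library medians, a fit without the intensity trend, and each library left out in turn. After the data were seen, 7 were added: the paired fit with a mean of at least 2 FPKM, with quantile normalisation, with the olfactory receptor background subtracted and with small RNA entries left out, the last 2 also without pairs, and library weights. Tests on whole-number reads were not run, since the deposited values are FPKM.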

Results

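RNA-seq profiles came from human brain, as 2 libraries of whole tissue and 2 libraries of a matched fraction enriched for microvessels, the small vessels whose endothelial cells form the blood-brain barrier. The submitters named this fraction brain microvessel endothelial cells. Libraries 1 and 2 of each group form pairs 1 and 2. The implied depth was 7.39 and 4.49 M reads in whole brain and 6.95 and 1.98 M in microvessels, so that microvessel 2 gave the least precise values. Olfactory receptor genes, taken as background, had a mean of 0.606 FPKM (95% interval 0.574 to 0.638) in whole brain 1, 0.904 (0.855 to 0.956) in whole brain 2, 0.587 (0.555 to 0.620) in microvessel 1 and 1.28 (1.19 to 1.37) in microvessel 2. The MTRNR2L genes, copies of mitochondrial ribosomal RNA in the nuclear genome, took 2.24% and 7.21% of all FPKM in whole brain and 4.96% and 23.7% in microvessels. These shares hold MTRNR2L8 at 0 in whole brain and at 4063 and 17390 FPKM in microvessels. That entry may be a failed estimate, as described below, and it adds to the difference between the groups.

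The comparison of the fractions asked which genes, and which ABC and SLC transporters among them, were enriched in microvessels over whole brain. Genes of the vessel wall were higher in microvessels. The 14 markers of pericytes and smooth muscle, the contractile cells around vessels, had a median log2 change of 2.20 (4.58-fold), and 14 of 14 were higher in both pairs. MYH11, a smooth muscle myosin, was at 3.56 ± 1.09 FPKM (SD, n = 2) in whole brain and 50.2 ± 41.4 in microvessels (n = 2 in each group throughout). RGS5, a pericyte marker, was at 80.9 ± 34.5 and 547 ± 95.4 FPKM, and PDGFRB, the pericyte receptor for PDGF-B, at 4.26 ± 2.64 and 20.3 ± 1.20. ACTA2, smooth muscle actin, was at 12.7 ± 2.46 and 256 ± 300. The 22 endothelial markers had a median log2 change of 1.60 (3.03-fold), and 20 were higher in both pairs. FLT1, a VEGF receptor, was at 43.3 ± 36.5 FPKM in whole brain and 161 ± 60.5 in microvessels, and ERG, an endothelial transcription factor, at 3.65 ± 1.92 and 16.1 ± 1.74. CLDN5, the main claudin of brain endothelial tight junctions, was at 4.52 ± 3.46 and 15.9 ± 1.84, and VWF, von Willebrand factor, was at 1.13 and 4.74 FPKM in whole brain and 9.44 and 14.6 in microvessels. The entry used for PECAM1 covers part of its locus (chr17, 62399864 to 62401205) and was at 21.1 and 29.6 FPKM in whole brain and 66.5 and 52.7 in microvessels.

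Both lists passed limma's camera at the preset correlation (adjusted p = 1.6e-18 for each). Neither passed when the correlation was estimated (adjusted p = 0.314 for each). In single-gene tests limma's unpaired fit called 0 members over all genes tested, with 13 mural and 14 endothelial markers higher at an unadjusted p under 0.05. Adjusted over the list alone, it called 10 mural and 14 endothelial markers. In the paired fit MYH11 (limma adjusted p = 0.0414), RGS5 (0.0370) and PDGFRB (0.0441) rose over all genes tested, as did FLT1 (0.0414), ERG (0.0441), CD34 (0.0441) and PODXL (0.0441). A call in the paired fit does not mean that the pairs agreed in size: MYH11 was 24.3-fold higher in pair 1 and 4.43-fold in pair 2. In that fit 14 mural and 19 endothelial markers passed adjusted over the list alone. The medians were higher in pair 1 than in pair 2 for mural (3.09 against 1.38) and endothelial markers (2.20 against 0.94), and endothelial markers were higher in whole brain 2 than in whole brain 1 by a median of 1.05 log2 units.

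**Figure D1:**
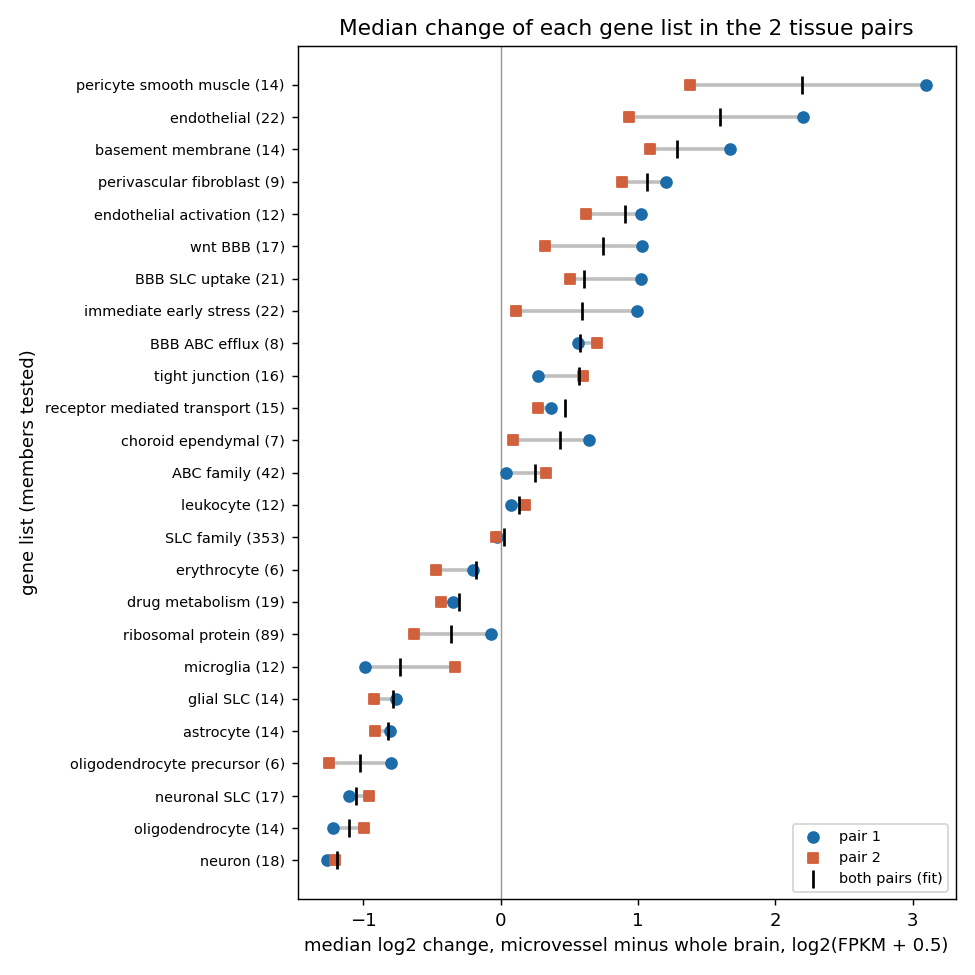
Median log2 change of each gene list, microvessel minus whole brain on the log2(FPKM + 0.5) scale (horizontal axis), for pair 1 (circles), pair 2 (squares) and both pairs together (vertical bars); the number of genes tested stands beside each name. Pericyte and smooth muscle markers lie highest (2.20) and neuron markers lowest (-1.19), while the sign of the leukocyte, erythrocyte, ribosomal protein, SLC family and ABC family medians changes with the scaling or when a library is left out.

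Matrix and junction genes of the vessel were higher too. The 14 basement membrane genes had a median log2 change of 1.28, with 14 of 14 higher in both pairs. COL4A1, a chain of the main vascular basement membrane collagen, was at 1.38 ± 0.658 FPKM in whole brain and 6.29 ± 0.582 in microvessels, and LAMA2, a laminin chain, at 3.30 ± 0.0931 and 11.4 ± 0.472. The 9 perivascular fibroblast markers had a median of 1.07 and 6 were higher in both pairs. Among them, COL1A2, a fibrillar collagen chain, was at 1.23 ± 0.886 and 9.78 ± 1.03 FPKM. The 17 genes of Wnt signalling at the barrier had a median of 0.75 with 13 higher in both pairs. LEF1, a transcription factor of that pathway, was at 5.03 ± 3.15 and 20.4 ± 3.75. The 16 tight junction genes had a median of 0.57 with 10 higher and 2 lower in both pairs. Beside CLDN5, MARVELD2, F11R and OCLN had log2 changes of 1.28, 1.27 and 1.06; with a library left out F11R ranged from 0.73 to 1.81 and OCLN from 0.63 to 1.48. All 4 lists passed camera at the preset correlation (adjusted p = 5.9e-12, 1.7e-06, 5.7e-05 and 0.0034 in that order) and none did with an estimated correlation (adjusted p = 0.314 for each). Adjusted over the list alone, the unpaired fit called 7 basement membrane and 4 fibroblast genes and the paired fit 9 and 4, all higher; for Wnt signalling and tight junction genes the counts were 0 and 0 unpaired and 3 and 1 paired. COL1A2 rose in the paired fit (limma adjusted p = 0.0414) and the other members named here did not pass over all genes. The fibroblast median was 2.11 with a mean of at least 2 FPKM and 1.62 with the background subtracted, and without microvessel 2 the tight junction median was 0.34.

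Markers of the brain's other cells were lower in microvessels. The 18 neuron markers had a median log2 change of -1.19 and 17 were lower in both pairs. SNAP25, a synaptic fusion protein, was at 3461 and 1002 FPKM in the whole-brain libraries and at 1579 and 409 in the microvessel libraries. NEFM, a neurofilament chain, was at 197 ± 146 and 49.5 ± 34.2. The 14 oligodendrocyte markers had a median of -1.11, with 12 lower in both pairs. SOX10, a transcription factor of this lineage, was at 43.3 ± 10.9 and 9.08 ± 1.89 FPKM. MBP, myelin basic protein, was at 5812 and 5940 in whole brain and 2583 and 5761 in microvessels. The 14 astrocyte markers had a median of -0.82, with 13 lower in both pairs. AQP4, the water channel of astrocyte endfeet, was at 162 ± 78.8 and 62.2 ± 44.2 FPKM. The 12 microglia markers had a median of -0.73, with 9 lower in both pairs. CX3CR1, the fractalkine receptor, was at 14.7 ± 9.93 and 2.84 ± 1.03. The 6 markers of oligodendrocyte precursors had a median of -1.03, with 4 lower and 2 higher in both pairs. Among the lower was PDGFRA, a growth factor receptor (15.5 ± 2.29 and 5.75 ± 0.235 FPKM).

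The neuron, oligodendrocyte, astrocyte, microglia and precursor lists passed camera at the preset correlation (adjusted p = 7.9e-06, 1.4e-05, 0.0010, 3.0e-04 and 0.043). With an estimated correlation none passed (adjusted p = 0.466, 0.314, 0.466, 0.314 and 0.569), and with pairs the precursor list did not pass (adjusted p = 0.058). The unpaired limma fit called 0 of these markers over all genes, with 2 neuron, 5 oligodendrocyte, 0 astrocyte, 2 microglia and 2 precursor markers lower at an unadjusted p under 0.05. It called 2 oligodendrocyte and 2 microglia markers as lower adjusted over the list alone. Called in the paired fit were NEFM (limma adjusted p = 0.0414), STMN2 (0.0429), THY1 (0.0441), RBFOX3 (0.0484), SOX10 (0.0414) and CX3CR1 (0.0487), which fell. Adjusted over the list alone, the paired fit called 15 neuron, 8 oligodendrocyte, 7 astrocyte, 2 microglia and 4 precursor markers, all lower. The neuron median depended on each library: it was -0.38 without whole brain 1, -2.12 without whole brain 2, -2.03 without microvessel 1 and -0.60 without microvessel 2. Neuron markers differed between the whole-brain libraries themselves by a median of -1.80 (2 minus 1). Under quantile normalisation the neuron, oligodendrocyte and astrocyte medians were -0.66, -0.59 and -0.46, and each list still passed camera at the preset correlation. The astrocyte median was -0.66 without microvessel 2 (adjusted p = 0.111). GFAP, an astrocyte filament gene with a log2 change of -0.51 ± 0.82 (SE), turned to 0.27 under quantile normalisation. The precursor median was -0.48 without whole brain 2 (adjusted p = 0.467) and -0.70 without microvessel 1 (adjusted p = 0.594).

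Among ABC transporters, pumps driven by ATP, the drug efflux pumps ABCG2 and ABCB1 had the highest log2 changes. ABCG2 (chr4, 89011417 to 89080011), the breast cancer resistance protein, was at 10.7 and 13.7 FPKM in whole brain and at 71.9 and 37.7 in microvessels, 6.45-fold higher in pair 1 and 2.69-fold in pair 2. ABCB1 (chr7, 87132948 to 87461612), P-glycoprotein, was at 1.14 and 6.50 FPKM in whole brain and at 20.1 and 12.2 in microvessels, 12.6-fold and 1.82-fold higher. ABCC9, the channel-regulating SUR2 subunit that is also on the pericyte list, was at 6.71 ± 0.656 and 15.9 ± 4.39, and ABCA9 at 3.32 ± 3.11 and 7.35 ± 1.33. The multidrug resistance proteins ABCC5 and ABCC4 were at 12.8 ± 2.14 and 21.6 ± 0.847 and at 1.58 ± 0.297 and 3.08 ± 0.878. In microvessels the 5 most abundant ABC genes were ABCG2, ABCC5, ABCB1, ABCC9 and ABCA2 (11.7 ± 4.41 FPKM), and in whole brain they were ABCA3, ABCA8, ABCC5, ABCA2 and ABCG2.

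Of the 42 ABC genes tested, 22 were higher and 12 lower in both pairs, and ABCG2 alone was at least 2-fold higher in both. The unpaired limma fit called 0 of them, over all genes or adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05. The paired fit called ABCG2, which rose (log2 change 2.06 ± 0.38 SE, limma adjusted p = 0.0472 over all genes and 0.0141 adjusted over the list alone). That call over all genes ended in the paired fit after quantile normalisation (log2 change 2.47, adjusted p = 0.0830) and with the background subtracted (2.12, adjusted p = 0.387). Among the 8 efflux genes fixed for the barrier, the unpaired fit called ABCB1 and ABCG2 as higher adjusted over the list alone (limma adjusted p = 0.0261 for both). In the paired fit the same 2 passed (0.0117 and 0.00268). With a library left out, the log2 change of ABCB1 ranged from 1.2 to 3.3. Over all genes tested, ABCB1 did not pass in the paired fit (log2 change 2.26 ± 0.57 SE, limma adjusted p = 0.0773). In paired fits it passed with a mean of at least 2 FPKM (0.0133) and with small RNA entries left out (0.0186). ABCG2 passed in these 2 settings too (limma adjusted p = 0.0047 and 0.0070). ABCB1 did not pass in the paired fit after quantile normalisation (0.1795) or with the background subtracted (0.4407). The largest negative log2 changes, at ABCA3 (-0.93), ABCG4 (-0.82), ABCF2 (-0.66) and ABCE1 (-0.57), did not pass either, and with a library left out they came as close to 0 as -0.52, -0.35, -0.26 and -0.23. The family's median log2 change of 0.25 passed camera at the preset correlation (adjusted p = 0.034), as did the median of 0.58 of the 8 efflux genes (adjusted p = 0.0040). With an estimated correlation neither did (adjusted p = 0.365 and 0.314). The family median was 0.15 without whole brain 1, 0.36 without whole brain 2 (adjusted p = 0.088), 0.49 without microvessel 1, -0.06 without microvessel 2 (adjusted p = 0.249) and 0.06 under quantile normalisation (adjusted p = 0.084).

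**Figure D2:**
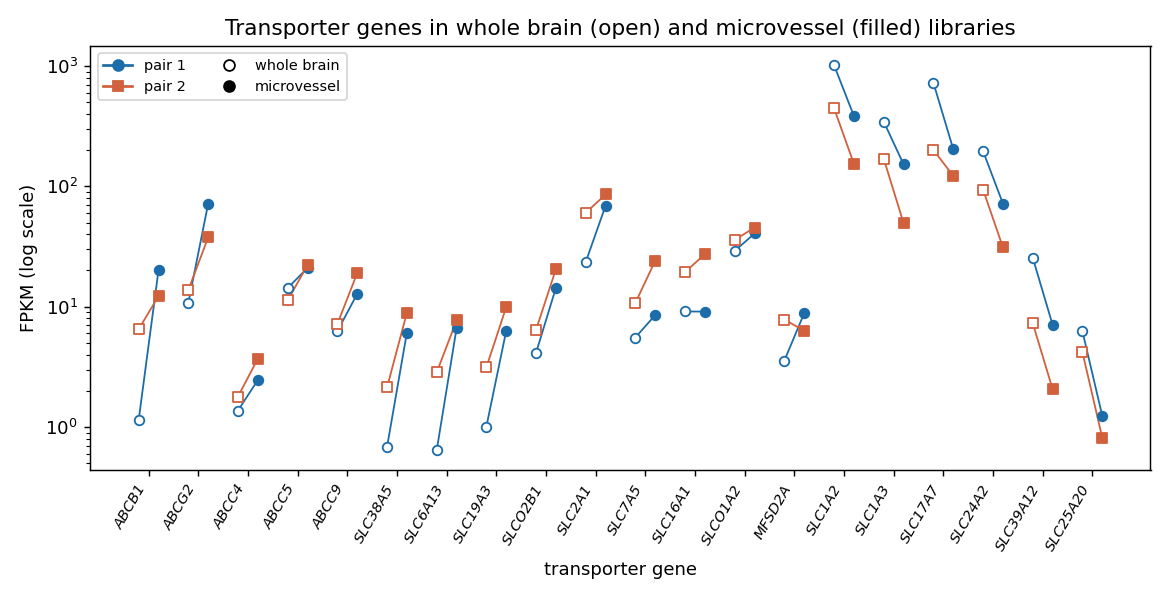
FPKM (vertical log axis) of 20 transporter genes in whole brain (open) and microvessels (filled), joined within pair 1 (circles) and pair 2 (squares); each symbol is 1 library. ABCG2 and SLC38A5 are higher and SLC1A2 and SLC24A2 lower in the microvessel library of both pairs, while MFSD2A is higher in pair 1 and lower in pair 2.

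SLC genes encode solute carriers. The 21 uptake carriers fixed for the barrier had a median log2 change of 0.61, with 11 higher and 3 lower in both pairs. SLC38A5 (chrX, 48316928 to 48328644), a glutamine carrier, was at 0.681 and 2.13 FPKM in whole brain and at 6.08 and 8.89 in microvessels, 5.57-fold and 3.57-fold higher. SLC6A13, a GABA carrier that is also on the perivascular fibroblast list, was at 1.74 ± 1.55 and 7.15 ± 0.772 FPKM. SLC19A3, a thiamine carrier, was at 2.07 ± 1.51 and 8.12 ± 2.56, and SLCO2B1, an organic anion carrier, at 5.28 ± 1.62 and 17.4 ± 4.36. SLC2A1 (chr1, 43391046 to 43449029), the glucose carrier GLUT1, was at 23.5 and 60.2 FPKM in whole brain and at 69.0 and 85.6 in microvessels.

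Lists of carriers known from neurons and glia were lower in median. The 17 neuronal SLC genes had a median log2 change of -1.06, with 14 lower in both pairs and 0 higher, and the 14 glial SLC genes of -0.78, with 12 lower and 2 higher. SLC1A2 and SLC1A3, the astrocyte glutamate carriers, were at 731 ± 404 and 257 ± 124 FPKM in whole brain and at 269 ± 163 and 101 ± 72.6 in microvessels. SLC17A7, the vesicular glutamate carrier of excitatory neurons, was at 463 ± 371 and 163 ± 57.6, and SLC24A2, a sodium, calcium and potassium exchanger, at 145 ± 72.1 and 51.4 ± 28.8. These brain carriers were nevertheless abundant in the microvessel fraction, and its 5 SLC genes of the highest mean were SLC1A2, SLC17A7, SLC1A3, SLC2A1 and SLC39A10. SLC25A20, a mitochondrial carnitine carrier, was at 5.21 ± 1.45 and 1.02 ± 0.298 FPKM and SLC25A5, an ADP/ATP carrier, at 31.9 ± 24.7 and 12.3 ± 15.2.

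Of the 353 SLC genes tested, 108 were higher and 119 lower in both pairs; 9 were at least 2-fold higher and 18 at least 2-fold lower in both. The unpaired limma fit called 0, over all genes or adjusted over the list alone, with 19 higher and 9 lower at an unadjusted p under 0.05. The paired fit called SLC38A5, which rose (log2 change 2.16 ± 0.40 SE, limma adjusted p = 0.0482), and that call ended after quantile normalisation (log2 change 2.14, adjusted p = 0.111) and with the background subtracted (2.81, adjusted p = 0.387). Adjusted over the list alone, it called SLC38A5, SLC6A13, SLC19A3 and SLCO2B1 as higher (limma adjusted p = 0.0368 for each) and 10 genes as lower: SLC1A2, SLC1A3, SLC24A2, SLC25A5, SLC25A20, SLC35F1, SLC38A1, SLC39A12 and SLC9A3R1 (0.0368 for each), the last a scaffold protein named after an exchanger, and SLC25A4 (0.0408). Among the 21 barrier uptake carriers, the unpaired fit called SLC38A5 (limma adjusted p = 0.0331), SLC6A13 and SLC19A3 (0.0393 for both) as higher adjusted over the list alone. With pairs, 8 of the 21 passed as higher, SLC2A1 included (0.0426), and 1 as lower. SLC2A1 (log2 change 1.02 ± 0.35 SE in the paired fit), the amino acid carrier SLC7A5 (0.85), the lipid carrier MFSD2A (0.46), SLCO1A2 (0.41) and the monocarboxylate carrier SLC16A1 (0.24) did not pass over all genes tested. With a library left out, SLC2A1 ranged from 0.35 to 1.69, SLC7A5 from 0.13 to 1.58 and SLCO1A2, which is also on the endothelial list, from 0.26 to 0.56.

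The uptake, neuronal and glial SLC lists passed camera at the preset correlation (adjusted p = 6.3e-05, 3.5e-05 and 2.6e-04) and not with an estimated correlation (adjusted p = 0.314, 0.466 and 0.466). The whole SLC family did not pass (adjusted p = 0.924), with a median of 0.02, a mean of -0.04 and a test direction below 0. The uptake median was 0.41 without whole brain 1 and 0.97 without whole brain 2, and the neuronal SLC median was -0.35 without whole brain 1 and -0.42 without microvessel 2. Under quantile normalisation the uptake median was 0.92 and the neuronal SLC median -0.62. SLC39A10 (log2 change -0.63) turned to 0.07 under quantile normalisation. The limma test fry passed none of the 25 lists in either fit (smallest adjusted p = 0.256 unpaired and 0.294 paired), and without microvessel 2 it passed 1, the immediate early and stress genes (adjusted p = 0.0252).

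Over all 19420 genes, the largest positive log2 difference after that of MTRNR2L8, described below, was at FHL5 (4.11). The most negative was at the small RNA entry MIR1977, a short locus (chrM, 5640 to 5716) where a few reads and the pseudocount set the value and its rank. FHL5, a LIM domain gene of contractile cells, was at 1.60 ± 1.05 FPKM in whole brain and 37.6 ± 24.3 in microvessels. NEAT1, the long RNA of nuclear paraspeckles, was at 14.2 ± 9.70 and 144 ± 58.7. The joined entry of LOC728264 and of MIR143 and MIR145, microRNAs of smooth muscle, was at 0.985 and 3.34 FPKM in whole brain and 38.0 and 18.4 in microvessels. It spans chr5, 148786440 to 148812399, and does not show which of the joined genes gave the reads. The pseudogenes HERC2P9 and HERC2P2, which share sequence with HERC2, were at 0.843 ± 0.413 and 16.4 ± 6.17 and at 1.94 ± 2.18 and 22.6 ± 15.8. SNORD81, a small nucleolar RNA entry, was at 0 and 0 FPKM in whole brain and 3.35 and 11.7 in microvessels. Its microvessel values stood in the same ratio as the FPKM of 1 read in these libraries. Both can thus rest on the same few reads, and the values of 0 in whole brain do not show a lower level. Lower were MIR1977, at 17.6 and 28.9 FPKM in whole brain and 1.87 and 0 in microvessels, and MIR1226, at 1.80 and 5.94 and at 0 and 0. The whole-brain values of MIR1226 stood in a ratio that 1 or a few reads give. Its values of 0 in microvessels therefore do not show a lower level. NPY, neuropeptide Y, was at 55.6 and 6.77 FPKM in whole brain and at 8.74 and 0 in microvessels. HHLA3 was at 21.1 ± 7.14 and 4.01 ± 4.78, and HIST1H4E, 1 of several near-identical H4 histone genes, at 34.8 ± 2.24 and 6.51 ± 5.41. The paired fit called each of these (limma adjusted p from 0.0283 to 0.0429) and the unpaired fit did not. HBB, a haemoglobin chain, was at 9.08 and 148 FPKM in whole brain and at 5.06 and 3.23 in microvessels and passed in neither fit.

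The unpaired limma fit called 1 gene as higher and 0 as lower; 1117 genes had an unadjusted p under 0.05, 710 higher and 407 lower. That number was 287 without whole brain 1, 791 without whole brain 2, 1989 without microvessel 1 and 560 without microvessel 2. The 1 call was MTRNR2L8 (chr11, 10529436 to 10530723; limma adjusted p = 1.3e-05), which was listed at 0 in both whole-brain libraries and at 4063 and 17390 FPKM in the microvessel libraries. The call was lost without whole brain 1 and without whole brain 2, which left 0 calls each, although its log2 difference, set by the pseudocount, stayed between 12.99 and 15.09. With the pairs as a block, 81 genes rose and 79 fell, 21 of the 160 being small RNA entries and 24 having a value of 0 in at least 1 library. The paired count turned on the setting. It was 359 and 688 with small RNA entries left out, 370 and 945 with a mean of at least 2 FPKM, but 1 and 0 after quantile normalisation and 0 and 0 after subtraction of the background. At least 2-fold changes in both pairs, with no test, were found in 501 genes that were higher and 737 that were lower.

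The sign of the change was the same in both pairs for 63.9% of genes, and the changes of the pairs correlated across genes, which are not independent replicates, with Pearson r = 0.356 and Spearman rho = 0.396. With the pairs crossed, 41.8% of genes had the same sign and Pearson r was -0.106. Between libraries, Pearson r was 0.921 for the whole-brain libraries and 0.833 for the microvessel libraries. Microvessel 1 had r = 0.917 with each whole-brain library, and microvessel 2 had r = 0.776 and 0.830. The median log2 change of all genes was -0.02, and it moved to -0.25 with a mean of at least 2 FPKM, to -0.11 with equal library medians and to -0.11 with the background subtracted.

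**Figure D3:**
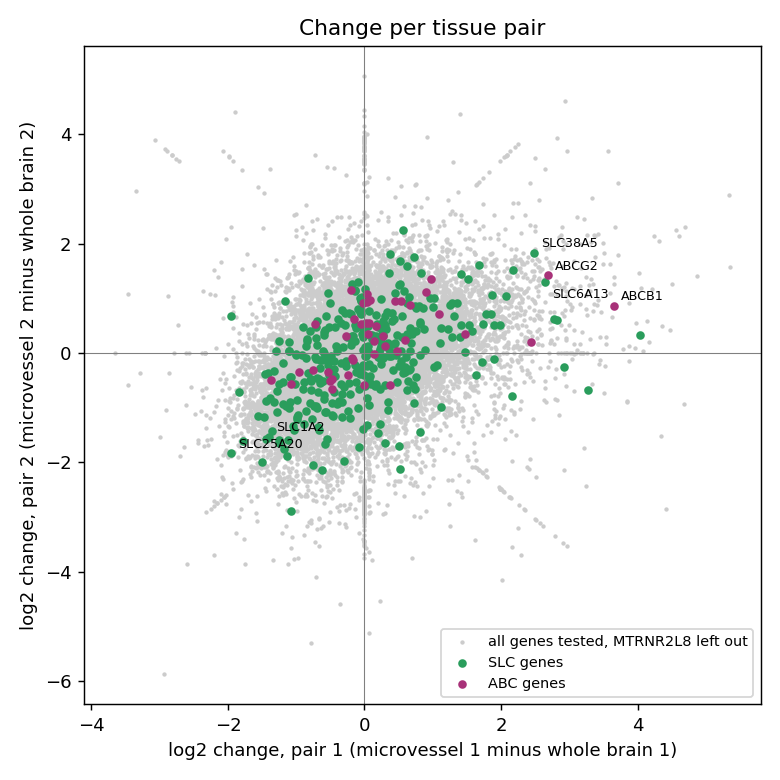
Log2 change, microvessel minus whole brain on the log2(FPKM + 0.5) scale, in pair 1 (horizontal axis) and pair 2 (vertical axis) for all genes tested (grey, without MTRNR2L8), SLC genes (green) and ABC genes (purple). Signs are the same in both pairs for 63.9% of genes; SLC38A5 and ABCG2 lie to the upper right and SLC1A2 and SLC25A20 to the lower left, and ABCB1 is farther from 0 in pair 1 than in pair 2.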

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

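Tests on the added alternatives (small RNA entries, background, library weights and the paired fits beyond the planned one) were chosen after the data were seen. Over 19 alternatives, 13 of the 20 gene lists past camera at the preset correlation stayed past it with the same direction in every one. Among these were the mural, endothelial, basement membrane, neuron, oligodendrocyte, microglia, neuronal SLC, glial SLC and both barrier transporter lists. With an estimated correlation 0 lists passed in any of them (smallest adjusted p = 0.25). With fry, 1 list passed in 1 alternative: immediate early and stress genes without microvessel 2 (adjusted p = 0.0252). The replicate block (paired fit) gave 81 genes higher and 79 lower, 1 ABC and 1 SLC gene higher, and, adjusted over the list alone, 1 ABC gene higher and 4 SLC genes higher with 10 lower. Among the lists past camera at the preset correlation it ended the call of the precursor markers and changed no other. Adjusted over the list alone, it called 10 neuronal SLC, 5 glial SLC and 2 drug metabolism genes as lower. It called 1 endothelial activation gene as higher. The unpaired fit called 0 in each of these 4 lists. With the block and a mean of at least 2 FPKM the counts were 370 and 945, with 3 ABC genes higher (3 adjusted over the list alone) and 8 SLC genes higher and 19 lower (11 and 32). With the block and small RNA entries left out they were 359 and 688, with 2 ABC genes higher (2) and 8 SLC genes higher and 16 lower (8 and 17). The fibroblast median of 1.07 became 2.11 with a mean of at least 2 FPKM and 1.62 with the background subtracted. Of the 160 paired calls, 145 were shared with the block and a mean of at least 2 FPKM and 139 with the block and small RNA entries left out. With the block after background subtraction, 0 were shared. Fewer genes were tested in the first 2 (12295 and 19073 against 19420). With small RNA entries left out, genes at an unadjusted limma p under 0.05 also rose, from 3827 to 4032. Fewer tests cannot give that rise, and the cause of these differences was not tested.

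Background subtraction gave 0 genes higher, with the block 0 too. Equal library medians gave 3 higher and 1 lower, and leaving out small RNA entries gave 3 higher. Adjusted over the list alone, quantile normalisation gave 1 ABC gene higher and, with the block, 2. Leaving out a library in turn gave 0 to 1 genes higher. The arm with 1 library was assumed to vary like the other. Signs were the same in both pairs for 61.8% of genes with no filter, 68.7% with a mean of at least 2 FPKM and 41.8% with crossed pairs.

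Directions turned as follows, with and without the block, and the cause was not tested. The leukocyte median was -0.58 with a mean of at least 2 FPKM and -0.0768 under quantile normalisation. There the ribosomal protein median was 0.0402 and the log2 changes of ABCA2, GFAP and SLC39A10 were 0.21, 0.27 and 0.0707. With a library left out, medians ranged from -0.28 to 0.68 for leukocyte, from -0.80 to 0.0933 for ribosomal protein and from -0.11 to 0.11 for SLC family genes. The SLC family median was also -0.30 with a mean of at least 2 FPKM, -0.15 with the background subtracted, -0.08 under quantile normalisation and -0.06 with equal library medians. The leukocyte median was -0.05 with the background subtracted, the ABC family median was -0.06 without microvessel 2, and the erythrocyte median was 0.13 without whole brain 2. With a library left out, log2 changes ranged from -0.48 to 0.28 for ABCA2, from -0.0570 to 0.97 for MFSD2A, from -4.76 to 0.45 for RPL39, from -0.53 to 1.009 for SLC16A1 and from -1.63 to 0.37 for SLC39A10. With the direction of a list taken from camera, which can differ from the sign of its median, 2510 results for lists and named genes stayed the same in call and direction, 159 gained a call, 25 lost it and 25 turned direction. Of the counts and summaries, 202 stayed and 35 moved. Tests on read counts were not run because the values are FPKM. At 1.98 M reads, a value of 0 for a 1 kb gene in microvessel 2 leaves levels up to 1.52 FPKM open.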

Other observations

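Tests of the 2 explanations for MTRNR2L8 and of the brain-cell RNA explanation for neuronal SLC genes were chosen after the result was seen. Genes of the early stress response were mixed. The 22 immediate early and stress genes had a median log2 change of 0.59, 0.99 in pair 1 and 0.12 in pair 2, with 11 higher and 5 lower in both pairs, and passed camera at the preset correlation (adjusted p = 0.0034; adjusted p = 0.466 with an estimated correlation). FOS, a transcription factor induced within minutes of stimulation, was at 5.34 and 1.14 FPKM in whole brain and 76.4 and 5.15 in microvessels and rose in the paired fit (limma adjusted p = 0.042). DUSP1, a phosphatase gene, was at 9.97 and 18.0 FPKM in whole brain and 153 and 34.2 in microvessels. KLF4, a transcription factor, was at 0.786 ± 0.394 and 12.9 ± 13.6 FPKM (SD, n = 2). Lower in both pairs were HSPH1 (log2 change -1.07), EGR1 (-1.05), DNAJB1 (-0.86), FOSB (-0.48) and EGR2 (-0.40). Adjusted over the list alone, the paired fit called FOS (limma adjusted p = 0.0040), KLF4 and DUSP1 (0.0144 for both) as higher and HSPH1 (0.0344) as lower. Without microvessel 1 the list median was 0.20 (adjusted p = 0.994). The 12 genes of endothelial activation had a median of 0.90 (adjusted p = 2.6e-04; 0.314 with an estimated correlation), with 10 higher in both pairs. IL6, an inflammatory cytokine, was at 0.344 and 3.58 FPKM in whole brain and 1.46 and 27.8 in microvessels, 2.33-fold and 6.92-fold higher. Its value in whole brain 1 lay below the olfactory receptor background there (0.606 FPKM), so the fold in pair 1 leans on the pseudocount. That median was 0.29 without microvessel 2, and without whole brain 1 it was 0.61 and did not pass (adjusted p = 0.108). The 15 genes of receptor-mediated transport had a median of 0.47 (adjusted p = 0.010; 0.314 with an estimated correlation). TFRC, the transferrin receptor, was at 16.1 ± 1.51 and 25.7 ± 7.87 FPKM and the caveolar gene CAV1 at 2.59 and 5.64 in whole brain and 30.9 and 5.59 in microvessels, a difference that microvessel 1 carried. The median was 0.23 without microvessel 2, and the list did not pass without whole brain 2 (adjusted p = 0.062) or microvessel 1 (0.168).

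Some genes outside the lists, chosen after their values were seen, passed in the paired fit. TBX18 and EBF1, transcription factors known from mural cells, were at 0.593 ± 0.556 and 9.39 ± 4.68 FPKM and at 2.13 ± 1.17 and 16.7 ± 4.63. MECOM, a factor of arterial endothelium, was at 2.85 ± 1.66 and 22.0 ± 3.30 and the protease gene ADAMTS1 at 5.34 ± 1.05 and 40.5 ± 16.5 (limma adjusted p from 0.037 to 0.0414). PVALB, parvalbumin, was at 31.5 ± 14.8 and 5.68 ± 0.526 FPKM and TAC3, tachykinin 3, at 16.9 ± 4.95 and 3.98 ± 1.07 (limma adjusted p = 0.0414 and 0.0441). SLCO1C1, a thyroid hormone carrier on the barrier uptake list, had a log2 change of -1.04 and was the 1 member that the paired fit called as lower adjusted over the list alone. Mural markers had a median log2 change 0.60 above that of endothelial markers (permutation p = 0.023 across genes, which are not independent). Without microvessel 1 the medians were closer, at 1.79 and 1.57. The 89 ribosomal protein genes had a median of -0.36 and passed (adjusted p = 0.0064; 0.673 with an estimated correlation). With a library left out it lay at -0.16 without whole brain 1 (adjusted p = 0.255), -0.64 without whole brain 2, -0.80 without microvessel 1 and 0.09 without microvessel 2 (adjusted p = 0.430), and at 0.04 under quantile normalisation.

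The remaining lists did not pass in the main fit with all libraries. The 7 choroid plexus and ependymal markers had a median of 0.43 (adjusted p = 0.064). It ranged from 0.32 to 0.55 with a library left out, at 0.53 without whole brain 2 and 0.55 without microvessel 2. This median was 0.22 with the background subtracted and 1.13 with a mean of at least 2 FPKM. The 19 drug metabolism genes had a median of -0.30 (adjusted p = 0.064), and passed without whole brain 2 (-0.69, adjusted p = 0.034) and without microvessel 1 (-0.56, adjusted p = 0.032). It was -0.06 without whole brain 1 (adjusted p = 0.419) and -0.04 without microvessel 2 (adjusted p = 0.680). The 6 erythrocyte genes had a median of -0.18 (adjusted p = 0.240) and passed without whole brain 1 (-0.58, adjusted p = 0.0016). HBB was at 148 FPKM in the whole-brain library that remained. Without whole brain 2 the median turned to 0.13. The 12 leukocyte genes had a median of 0.13 and a mean of -0.06 (adjusted p = 0.924), and PTPRC, the common leukocyte antigen, was at 4.30 ± 1.63 and 2.62 ± 0.258 FPKM. Many of these genes lay near the olfactory receptor background of 0.587 (microvessel 1) to 1.28 FPKM (microvessel 2), so this list says little about leukocytes.

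MTRNR2L8 was listed at 0 in both whole-brain libraries and at 4063 and 17390 FPKM in microvessels. A failed estimate in the deposited table is a candidate explanation: the other 8 MTRNR2L genes with values above 0 in every library, which share much of its sequence, had a median log2 change of 0.48 (0.38 to 0.64). Higher expression of this gene in microvessels cannot be told apart from that, because whole brain gives no ratio to compare. In microvessels its ratio to MTRNR2L1 was 1.03 and 0.944, which differ by a factor of 1.10.

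Microvessel 2 stood apart from the other 3 libraries. Lower depth and a higher background were checked among 2455 genes with a mean of at least 20 FPKM over all libraries. There the mean correlation of microvessel 2 with the others was 0.566 against 0.701 for microvessel 1, a difference of -0.135 (bootstrap 95% interval -0.156 to -0.115). Over all genes tested the difference was -0.0759. The gap was thus not limited to genes of a low mean. Neither explanation is excluded, because correlations fall when the range of expression narrows. Microvessel 1 itself had 0.889 over all genes tested. A high mean over all libraries also does not ensure many reads in microvessel 2. Of the 2355 genes with a transcript length, 623 were under 1 kb. A loss of short transcripts stays open. Spearman rho between transcript length and the log2 ratio of microvessel 2 to microvessel 1 was 0.229 (0.189 to 0.264, across 2355 genes), an interval that spans the bound set for it, and the whole-brain libraries gave 0.169 for 2 against 1. A difference between the tissue samples was not tested.

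Neuronal SLC genes were lower in microvessels. A loss of short transcripts is argued against as the whole cause, since their median lay at the 0.04 percentile of 10000 random lists matched on transcript length and expression, whose median was -0.44. The genes of the random lists were drawn independently, while the estimated inter-gene correlation of the neuronal SLC list was 0.65. The percentile thus measures the drawing of genes and no spread between samples. Less RNA of brain cells in the enriched fraction would also lower other brain-cell markers. The neuron, oligodendrocyte, astrocyte and microglia medians were -1.19, -1.11, -0.82 and -0.73. Regulation of the neuronal SLC genes beyond this cannot be told apart from it. Their median was 0.18 above that of neuron markers (0.0090 to 0.905, with 15 and 16 genes at -0.99 and -1.17), an interval too wide to set within or beyond 0.5. It is a hypothesis that the signal of brain-cell carriers such as SLC1A2 in the microvessel fraction may come from astrocyte and neuron RNA left in it, and SNAP25 at 994 ± 827 FPKM there is a level that vessel cells are not known for. Single-cell sequencing of the fraction would decide this. No biological explanation was tested apart from these.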
